A study of Mus musculus with 16 samples.

How the data were processed

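RNA-seq, ATAC-seq and CUT&RUN libraries of FACS-sorted progenitors from the mouse cochlea were analysed, 16 in all. The E12.0 cells were Sox2-GFP positive and the E13.5 cells p27-GFP positive. The titles give the ages E12.0 and E13.5, while the protocols round them. Per the labels' protocols, RNA was selected for poly(A) and made into TruSeq libraries. CUT&RUN cuts chromatin around an antibody-bound protein and sequences the released fragments. Per the labels, the KAPA HTP kit was used for replicate 1 of H3K27ac and of Tead at E12.0, and the Accel 2S Plus kit with molecular identifiers for the other CUT&RUN libraries. Groups and replicate numbers were taken from the sample titles.

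The deposited RNA tables hold expected counts per Ensembl gene, estimated reads that need not be whole, with the gene's length and effective length in bases per the file headers. The tool that wrote them is not given in the sources used here. The peak lists were deposited as 1 list per library, with replicates not pooled. Each peak carries a fold (the ratio of signal over the local background at its summit) as deposited by the authors. It also carries −log10 p and −log10 q within that library, as deposited by the authors. A score in the deposited lists, 10 times −log10 p in the E12.0 ATAC lists and never above 1000 in the other lists, was not used. The submitters' processing notes name STAR, UMI-tools, MACS2 and the builds GRCm38 and mm10, which are names of the same assembly, without versions. The smallest deposited −log10 p was 2.00 to 2.51 by library, a permissive limit. In the E12.0 ATAC lists peak numbers ran without gaps and 58 to 90 peaks lay on unplaced contigs. In the other lists, E13.5 ATAC included, 46 to 250 peak numbers were missing and no contig appeared, so the authors' filters differed between the ATAC stages. Fold and −log10 values served only to rank or filter peaks within a list.

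Expected counts were rounded to whole numbers. Genes were kept by filterByExpr (15982 of 48709), scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, 2 against 2 libraries, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Gene symbols were matched for 48349 of the 48709 identifiers. Fixed gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over 21 lists with at least 2 measured genes. Genes with no count in a group were given a fold bound against 3 counts over the group, which is 0.19 CPM at E12.0 and 0.0673 at E13.5. A count of 10 reads corresponded to 0.424 to 1.38 CPM. Bounds and intervals cover counting error only. TPM was computed from the expected counts and effective lengths, and entered limma as log2(TPM + 1). On simulated counts for the E13.5 against E12.0 comparison (10 draws, 200 changed genes, a median of 15534 genes tested) the edgeR step recovered 2.4% of 1.5-fold, 15.4% of 2-fold, 77.4% of 4-fold and 93.6% of 8-fold changes, and a mean of 6.84% of its calls were false (2.06 to 13.7% by draw), above the nominal 5%. A first single draw had given a higher share than this mean, and the 10 draws were run after it was seen. Small changes were mostly missed in this simulation. In the data 7340 of 15982 genes were called, far above the 200 changed there. The adjustment then asks for a less extreme p, so these recovery and false-call shares need not hold for the data.

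The deposited expected counts of replicates differed by more than sampling noise (chi-square per degree of freedom 31.1 at E12.0 and 52.4 at E13.5), so each library was counted once. Log counts correlated at 0.948 to 0.959 within a stage and 0.715 to 0.755 across stages. The median of length minus effective length, which follows fragment size, was 146 and 141 bases at E12.0 and 189 and 188 at E13.5.

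For each assay the intervals of all libraries were merged, and a library held a region when one of its intervals overlapped it by 1 bp or more. A region was called at 1 stage when all libraries of that stage and none of the other held it. The functions were tested on made-up intervals. Tead regions were those held by both libraries, and the background was the same regions shifted by 10 kb in both directions. Genes came from a RefSeq table of GRCm38.p6 with 21887 protein-coding entries. Because that table gives no strand, distances run to either end of a gene's span where the design named the transcription start, and exons and introns were not separated. Random lists were drawn 10000 times within 10 bins of gene length for Tead regions, and 10000 times within 20 bins of mean expression for RNA. The Tead motif comparison was not run, because no genome sequence was used here.

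Gene lists, main tests, the first set of other settings and the rule for naming genes were fixed before the data were examined. Settings added later are named with the sensitivity results. The rule took the genes of the sorting reporters, 11 genes fixed beforehand, up to 4 members per list by smallest adjusted p, the 8 largest rises and falls among protein-coding genes with at least 10 CPM in the higher group and no overlap between groups, the 5 strongest Tead regions, the 10 strongest Tead regions near list genes and the 5 strongest stage-only regions near list genes. Where the text names fewer, the rest are in the counts. One gene that the rule takes is not reported here. Alternatives were DESeq2 size factors, no expression filter, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma on log2(TPM + 1), a minimum of 2-fold, an estimated correlation, fry, a distance of 10 kb, a background of genes near any region, equal-length lists by −log10 p, a −log10 q of at least 5, a 50% overlap, 2 of 3 libraries and regions under 2 kb.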

Results

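The series measured gene expression, open chromatin, a histone mark and Tead binding in progenitor cells of the mouse organ of Corti, the sensory epithelium of the cochlea. Its title names Yap/Tead and progenitor self-renewal as the subject. Yap is a transcriptional co-activator restrained by the Hippo kinase cascade, and Tead proteins are the DNA-binding factors it acts through. Cells were sorted by FACS for Sox2-GFP at E12.0 and for p27-GFP at E13.5, so embryonic age and sorting reporter change together and every stage difference below belongs to both. The 16 libraries comprise RNA-seq of 2 libraries per stage, ATAC-seq of 3 per stage, CUT&RUN for H3K27ac of 2 per stage, and CUT&RUN for Tead of 2 at E12.0. Summed expected counts were 9412287 and 9810541 in the E12.0 RNA libraries and 17057725 and 19570863 in the E13.5 libraries. The labels do not say whether replicates came from separate litters, so p-values measure the spread between these libraries.

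The cells of E13.5 had higher RNA of the genes behind both sorting reporters and of the Notch ligand gene Jag1. Only the E13.5 cells were sorted for p27-GFP, so higher RNA of the p27 gene can follow from the sort alone. With TMM scaling they had lower RNA of cell cycle genes and of the Yap1, Wwtr1 and Tead1 genes. The cell cycle list calls were lost with an estimated correlation (camera adjusted p = 0.511 to 0.664), and Yap1 and Tead1 were not called on log2(TPM + 1) (limma adjusted p = 0.146 and 0.981). With an estimated correlation camera uses only the residual degrees of freedom of these few libraries, and it called 0 of 21 lists. A call lost in that setting therefore decides little. Of 15982 genes tested, 7340 changed (edgeR quasi-likelihood test, adjusted p threshold 0.05), 3579 of them higher and 3761 lower at E13.5. Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27 (chromosome 6, 134920401 to 134925525, GRCm38), went from 8.15 ± 0.629 to 205 ± 32.7 CPM (TMM-scaled reads per 1e+06, SD, n = 2 per stage), a log2 fold change of 4.65 ± 0.30 (SE, edgeR adjusted p = 6.09e-06). Sox2, a transcription factor of the prosensory domain (chromosome 3, 34649995 to 34652461), went from 38.1 ± 1.82 to 160.5 ± 11.5, a log2 fold change of 2.07 ± 0.25 (edgeR adjusted p = 0.000132). On log2(TPM + 1) with limma the split was 6806 higher and 2309 lower, and the median of all genes lay at 0.75 against 0.05 with TMM scaling, so levels below are relative to TMM. The mitochondrial ribosomal RNA mt-Rnr2, chosen after its values were seen, took 17.0% and 13.2% of the counts at E12.0 against 0.295% and 0.18% at E13.5.

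**Figure D1:**
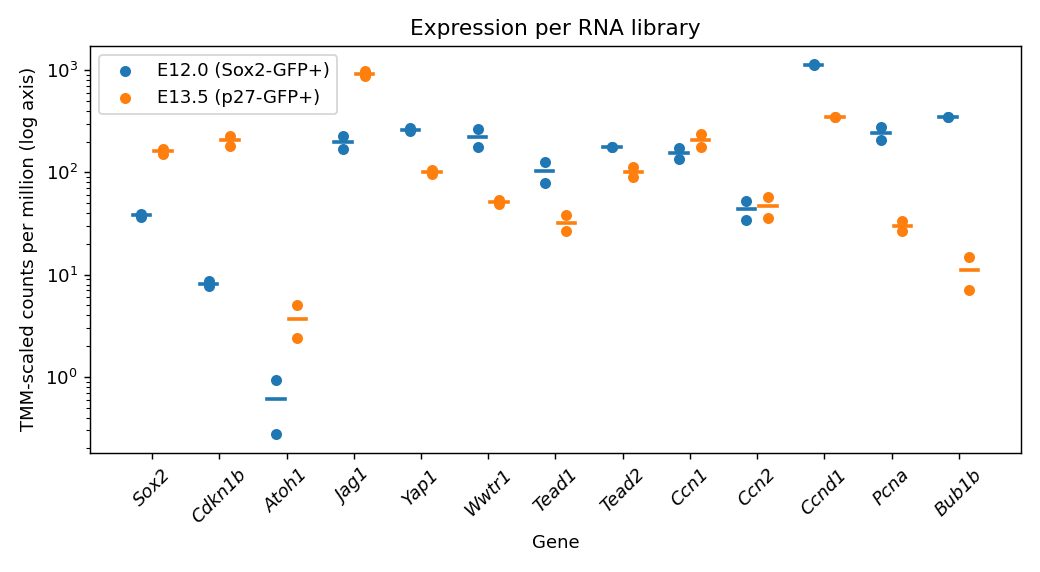
TMM-scaled CPM on a log axis for selected genes in each RNA library, with a point per library (n = 2 per stage) and a bar at the stage mean. The E13.5 libraries lie above the E12.0 libraries for Cdkn1b (205 against 8.15) and below them for Bub1b (10.98 against 348).

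Cell cycle genes were lower at E13.5, in libraries that also differed between E12.0 and E13.5 in the share of mt-Rnr2, as given above, and in the median of length minus effective length (146 and 141 against 189 and 188 bases). All 25 genes of the G2/M list, which act in mitosis and its preparation, fell, with a median log2 fold change of -3.24 (camera adjusted p = 6.9e-21). The adjusted p was 0.664 with an estimated correlation. Ube2c, a mitotic ubiquitin-conjugating enzyme, changed by -5.20 ± 0.41 (SE). The spindle checkpoint kinases changed by -4.98 ± 0.38 for Bub1b, -3.75 ± 0.30 for Bub1 and -3.74 ± 0.30 for Ttk. Of 25 S-phase genes, 21 fell and none rose, with a median of -1.94 (camera adjusted p = 1.56e-07). The adjusted p was 0.511 with an estimated correlation. Among them were the replication clamp Pcna at -3.02 ± 0.28, cyclin E1 (Ccne1) at -3.35 ± 0.31, the helicase subunit Mcm7 at -3.23 ± 0.31 and the ribonucleotide reductase subunit Rrm2 at -2.50 ± 0.28. Of 13 measured genes of G1 progression, 8 fell and 1 rose, with a median of -1.73 (camera adjusted p = 0.0107). The call was lost with an estimated correlation (adjusted p = 0.664) and on log2(TPM + 1), where the median was -0.71 (camera adjusted p = 0.0652). Cyclin D1 (Ccnd1) went from 1134 ± 3.51 to 350.3 ± 0.842 CPM, a log2 fold change of -1.69 ± 0.24 (edgeR adjusted p = 0.000389). Cdk2 changed by -2.62 ± 0.31, Cdk6 by -2.70 ± 0.34 and Skp2, part of the ubiquitin ligase that targets p27, by -1.99 ± 0.25, while Mycl rose. Myc had a log2 fold change of -2.32 ± 0.997 and did not pass (edgeR adjusted p = 0.08). Adjusted over the list alone, the lower counts were 25 for G2/M, 21 for S phase and 10 for G1, the last beside 2 that rose.

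Of 11 measured cell cycle inhibitors, 3 rose and 2 fell, and the list was not called (median log2 fold change 0.07, camera adjusted p = 0.527). Besides Cdkn1b, the stress-response gene Gadd45g changed by 1.02 ± 0.32, Cdkn1a, which encodes p21, by -1.08 ± 0.36, and the pocket protein gene Rbl1 by -1.43 ± 0.32 (SE, n = 2 per stage). The call of Gadd45g was lost without E12.0 replicate 1 (edgeR adjusted p = 0.0784), E12.0 replicate 2 (0.0728) or E13.5 replicate 2 (0.192). That of Cdkn1a was lost without E12.0 replicate 1 (0.119) or E13.5 replicate 2 (0.157), and on log2(TPM + 1) Cdkn1a lay at 0.47. Rbl1 lost its call without E12.0 replicate 2, at -0.96. On log2(TPM + 1) it lay at -0.39 and was not called (limma adjusted p = 0.483). With p adjusted over the list alone, 3 rose and 2 fell.

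The Yap and Tead genes were measured to ask how the pathway stands at each stage. Yap1 (chromosome 9, 7931999 to 8004638) went from 261 ± 11.9 to 101 ± 5.30 CPM (SD, n = 2), a log2 fold change of -1.37 ± 0.24 (edgeR adjusted p = 0.0011). Its paralog Wwtr1, which encodes Taz, went from 224 ± 63.5 to 51.3 ± 3.13, a change of -2.12 ± 0.28 (edgeR adjusted p = 0.000215). Tead1 changed by -1.68 ± 0.32 (edgeR adjusted p = 0.00187) and Tead2 by -0.80 ± 0.24 (0.0207). Tead3 at 0.31 ± 0.56 and Tead4 at -0.90 ± 0.87 did not pass. On log2(TPM + 1), where the median gene lay at 0.75, Yap1 was at -0.51, Tead1 at -0.01 and Tead2 at 0.21, none of them called. The call of Tead2 was also lost without E12.0 replicate 1 (edgeR adjusted p = 0.0758), E12.0 replicate 2 (0.0721) or E13.5 replicate 2 (0.129). Of the 22 Hippo pathway components measured, 9 fell and 4 rose, with a median of -0.43 that was 0.38 on log2(TPM + 1) (camera adjusted p = 0.527). The angiomotin gene Amot changed by -2.37 ± 0.31 and the Hippo kinase adaptor Sav1 by -2.35 ± 0.35. The counts adjusted over the list alone were again 9 and 4.

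The 21 measured targets of Yap and Tead were not called as a group (median log2 fold change -0.47, camera adjusted p = 0.527), with 6 lower, 2 higher and 13 that did not pass. The median had the opposite sign on log2(TPM + 1), at 0.31. The targets that fell included Amotl1 at -1.53 ± 0.24 (SE), the junction adaptor Ajuba at -1.47 ± 0.26 and the growth factor gene Tgfb2 at -1.89 ± 0.35, and Ccdc80 rose by 1.33 ± 0.25. On log2(TPM + 1) Amotl1 at -0.67 and Ajuba at -0.61 were not called. The commonly used readouts of the pathway did not pass. Ccn2 (also called Ctgf) stood at 43.6 ± 12.9 and 46.5 ± 14.8 CPM at E12.0 and E13.5 (edgeR adjusted p = 0.841, SD, n = 2). Ccn1 (also called Cyr61) stood at 154 ± 26.9 and 208 ± 41.3 (edgeR adjusted p = 0.198). The list-alone counts, adjusted over the list alone, were 6 lower and 2 higher.

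Of 20 measured prosensory genes, 10 rose and 5 fell, and the list was not called (median log2 fold change 0.87, camera adjusted p = 0.32). Fry, which asks whether the genes move on balance one way, gave an adjusted p of 0.0261. The Notch ligand gene Jag1 changed by 2.21 ± 0.27 (SE), while the inhibitor of differentiation Id1 changed by -2.16 ± 0.28 and the Notch effector Hes1 by -2.41 ± 0.32. Adjusted over the list alone, 10 rose and 6 fell. Among 8 measured hair cell genes, 2 rose and 2 fell (median 0.03, camera adjusted p = 0.994). Atoh1, the transcription factor that drives hair cell fate, went from 0.608 ± 0.471 to 3.71 ± 1.88 CPM (SD, n = 2), a log2 fold change of 2.57 ± 0.90 (edgeR adjusted p = 0.0387). That call was lost without E12.0 replicate 1 (edgeR adjusted p = 0.187) or E13.5 replicate 2 (0.273) and with DESeq2 (0.0525). Myo7a, a stereocilia motor, changed by 1.61 ± 0.47 and Espn, an actin bundler, by -1.69 ± 0.51. Myo7a was not called without E12.0 replicate 2 (0.0838) or E13.5 replicate 1 (0.0654), and Espn was not called without E12.0 replicate 1 (0.184) or E13.5 replicate 1 (0.0743), nor on log2(TPM + 1) (0.26). The Notch ligand gene Dll1 had 4.65 CPM at E12.0 and no count at E13.5, which makes it at least 69.1-fold lower against a floor of 3 counts over the group. The counts adjusted over the list alone were 3 and 2 for hair cell genes.

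Supporting cell genes moved both ways, 3 up and 3 down of 14 measured (median log2 fold change 0.03, camera adjusted p = 0.936). The tectorial membrane genes Tectb and Otogl changed by 2.93 ± 0.46 and 3.10 ± 0.57 (SE), Slc1a3, a glutamate transporter gene, by 1.37 ± 0.24, and S100a1 by -1.69 ± 0.31, a call lost on log2(TPM + 1) (limma adjusted p = 0.0644). Of 14 Notch pathway genes 2 rose and 6 fell (median -0.75, camera adjusted p = 0.651), the largest rise being Rfng, a glycosyltransferase of Notch, at 4.66 ± 0.43. The Notch list median was 0.39 on log2(TPM + 1). Wnt targets were split, with 2 up and 2 down of 8 (median 0.13, camera adjusted p = 0.994). Lgr5 changed by 1.501 ± 0.26 and Axin2 by -2.35 ± 0.39. Of 6 Hedgehog targets, 2 rose and 1 fell (median 0.75, camera adjusted p = 0.51), with Gli1 at 1.91 ± 0.35 and Gli3 at -1.02 ± 0.25, which lay at -0.02 on log2(TPM + 1). Adjusted over the list alone, the counts higher and lower were 3 and 3 for supporting cells, 2 and 7 for Notch, 2 and 2 for Wnt, and 3 and 1 for Hedgehog.

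Markers of other cells the sorted population could hold were measured too. No gene of the endothelial, erythroid or immune lists passed the expression filter. Of 10 neuronal genes, 3 fell and 1 rose (median log2 fold change -1.36, camera adjusted p = 0.57). Fry called this list lower (fry adjusted p = 0.0153), while its median was 0.0165 on log2(TPM + 1). Neurod1 had 10.7 CPM at E12.0 and a single library with 0.0424 at E13.5, and Isl1, which prosensory cells also express, rose by 1.36 ± 0.25 (SE). Of 8 mesenchymal genes 2 fell, Lum at -1.55 ± 0.26 and Postn at -1.93 ± 0.48 (not called on log2(TPM + 1), limma adjusted p = 0.0755), and none rose (median -0.17, camera adjusted p = 0.936). That median had no stable sign, at -1.38 to 1.78 with a library left out and 0.25 on log2(TPM + 1). Of 6 glial and neural crest genes 2 rose and 1 fell (median -0.28, camera adjusted p = 0.994), with Sox10 at 1.92 ± 0.24 and the receptor gene Erbb3 at -2.06 ± 0.26. The other gene that rose, Cdh19, stood at 0.0688 and 1.56 CPM, and its call was lost with DESeq2 (DESeq2 adjusted p = 0.0694). Whether the Sox10 and Erbb3 RNA came from glia was not tested. The melanocyte gene Dct had no count at E12.0 and 2.05 and 16.5 CPM in the E13.5 libraries, at least 48.7-fold higher, as 1 of 2 measured genes of its list that passed (median 4.33, or 2.07 with Dct at its bound, camera adjusted p = 0.883). Melanocyte genes below the expression filter had most of their counts in E13.5 replicate 2, with 2, 1, 12 and 158 for Pmel, 0, 0, 3 and 57 for Tyr, 0, 0, 0 and 28 for Tyrp1 and 0, 0, 0 and 10 for Mlana in E12.0 replicates 1 and 2 and E13.5 replicates 1 and 2, and the bound for Dct rests mainly on that library. General epithelial genes moved both ways, 2 up and 2 down of 7 (median 0.22, camera adjusted p = 0.994). The splicing regulator Esrp1 changed by -3.11 ± 0.26, Epcam by -1.40 ± 0.28 (not called on log2(TPM + 1), limma adjusted p = 0.121) and the claudin gene Cldn3 by 4.14 ± 0.37. Nonsensory epithelial genes had 1 up and 1 down of 6 (median -0.01, camera adjusted p = 0.994), with Otx2 at -2.80 ± 0.49. Medial epithelial genes had 1 up and 1 down of 5 (median -0.02, camera adjusted p = 0.744), with Tecta at 3.43 ± 0.27 and Epyc at -3.36 ± 0.67. Fry called the medial list higher (fry adjusted p = 0.0411). Immediate early genes of dissociation stress had 4 up and 1 down of 14 (median 0.76, camera adjusted p = 0.457), with Jun at 2.19 ± 0.24, Ier2 at 1.69 ± 0.29 and Fosb at -2.19 ± 0.46 (not called on log2(TPM + 1), limma adjusted p = 0.0811). Of 13 mitochondrial genes, 12 rose and 1 fell, with a median of 2.14 (camera adjusted p = 1.56e-07). The adjusted p was 0.797 with an estimated correlation. Adjusted over the list alone, the higher and lower counts were 1 and 3 for neurons, 0 and 2 for mesenchyme, 2 and 1 for glia, 1 and 0 for melanocytes, 2 and 2 for epithelium, 1 and 1 for each of the nonsensory and medial lists, 4 and 1 for stress and 12 and 1 for mitochondria.

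**Figure D2:**
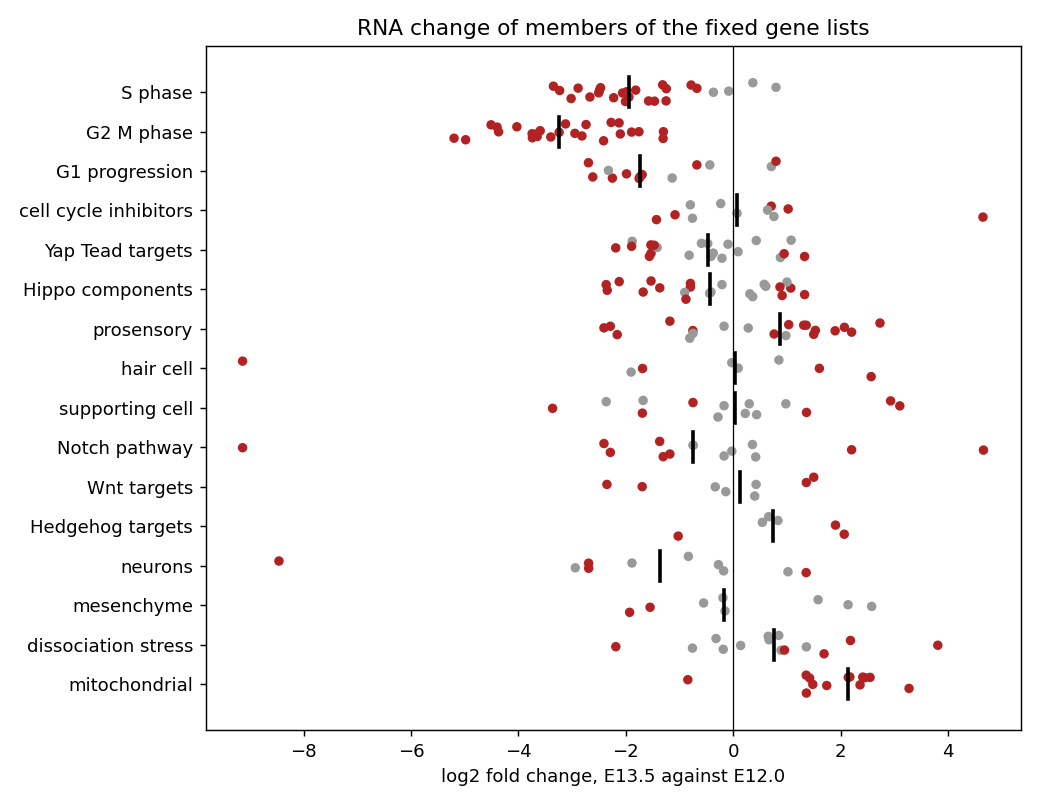
Log2 fold change of E13.5 against E12.0 for each measured member of 16 of the lists, with members past the edgeR adjusted p of 0.05 in red, the others in grey and the list median as a black bar. The G2/M list lies farthest to the left with a median of -3.24, and the mitochondrial list lies to the right at 2.14. Dll1, with no count at E13.5, is drawn at its fitted value.

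The largest rises among protein-coding genes included genes with no count at E12.0, Evi2 (at least 74.0-fold higher) and Ccdc85b (at least 53.0-fold higher), whose place in the ranking the bounds do not settle. Cpxm2, a carboxypeptidase-like gene, rose by 6.40 ± 0.37 on the log2 scale (SE), from 2.11 ± 0.322 to 178 ± 48.8 CPM (SD, n = 2). Sntb1, a syntrophin, rose by 6.40 ± 0.43, Apold1 by 6.71 ± 0.60 and Lor by 7.12 ± 0.73. Apold1 (chromosome 6, 134982001 to 134986836) lies near Cdkn1b, the gene of the p27 sorting reporter. Gna14 stood at 0.196 and 31.4 CPM and Duxbl3 at 0.0688 and 15.7. The largest falls were led by Gm20594, with 281 ± 6.99 CPM at E12.0 and no count at E13.5, at least 4171-fold lower. Bak1, a pro-apoptotic pore protein, changed by -6.83 ± 0.52, from 39.5 ± 1.76 to 0.344 ± 0.187 CPM. The linker histone genes Hist1h1b and Hist1h1d went from 18.2 and 22.7 CPM to 0.0926 and 0.0424, Gm6749 from 17.6 to 0.0476, and Kifc5b from 16.3 to 0.045. Apom changed by -6.93 ± 1.37, but its E12.0 libraries stood at 23.0 and 1.29 and its call was lost without E12.0 replicate 1 (edgeR adjusted p = 0.214). Gm20594, Gm6749, Kifc5b, Duxbl3 and the histone genes may have similar copies among which reads could be split. This was not measured, so their values are uncertain.

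Many more regions were called open at E13.5 only than at E12.0 only. Near list genes, the 5 strongest were nearest Stk3, Yap1, Amotl1, Notch2 and Kif20b. Merging the peaks of the 6 libraries gave 335380 regions. Of these, 22138 were called in all 3 E13.5 libraries and no E12.0 library, 181 in all 3 E12.0 libraries and no E13.5 library, and 33763 in all 6. Those nearest a gene of the fixed lists within 50 kb numbered 256 at E13.5 and 0 at E12.0. The strongest, by the smallest of the authors' 3 fold values, lay inside the span of the Hippo kinase gene Stk3 (chromosome 15, 34904517 to 34905101, smallest fold 10.02), 4987 bp from an end of Yap1 (chromosome 9, 7926058 to 7927012, 8.89), and inside Amotl1 (chromosome 9, 14648053 to 14648998, 8.84) and Notch2 (chromosome 3, 98127474 to 98128159, 7.10). The next lay 41520 bp from Kif20b (chromosome 19, 35017270 to 35017865, 6.91). By list, E13.5-only regions were 35 of 463 regions nearest Hippo components, 31 of 472 nearest prosensory genes, 28 of 495 nearest Yap and Tead targets, 25 of 296 nearest neuronal genes, 20 of 234 nearest mesenchymal genes, 18 of 293 nearest supporting cell genes and 15 of 244 nearest Notch genes. Hair cell genes had 13 of 256, G1 genes 10 of 185, cell cycle inhibitors 8 of 144 and all genes 10658 of 196738. Endothelial genes had 9 of 113, immune genes 7 of 83, medial genes 7 of 73 and erythroid genes 2 of 22. Wnt targets had 4 of 233 and stress genes 3 of 128. The order of the lists follows the counts and not the shares. No list was tested for enrichment. The bases shared by 2 lists made up 0.287 to 0.327 of the bases in either list among E12.0 replicates and 0.567 to 0.590 among E13.5 replicates. Between stages they made up 0.382 to 0.401 for E12.0 replicate 2 and 0.250 to 0.272 for E12.0 replicates 1 and 3. The E12.0 lists were shorter, with 99248 to 119970 intervals against 151927 to 161637. With the strongest 99000 intervals of each library the counts were 11335 and 262. Requiring 2 of 3 libraries gave 44664 and 2963, and the E12.0-only count was 1008, 1017 and 1294 without E12.0 replicate 1, 2 or 3. The E13.5-only count was 36378 without E12.0 replicate 2. Of the 181 E12.0-only regions, 25 lay on unplaced contigs, which only the E12.0 lists contain.

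**Figure D3:**
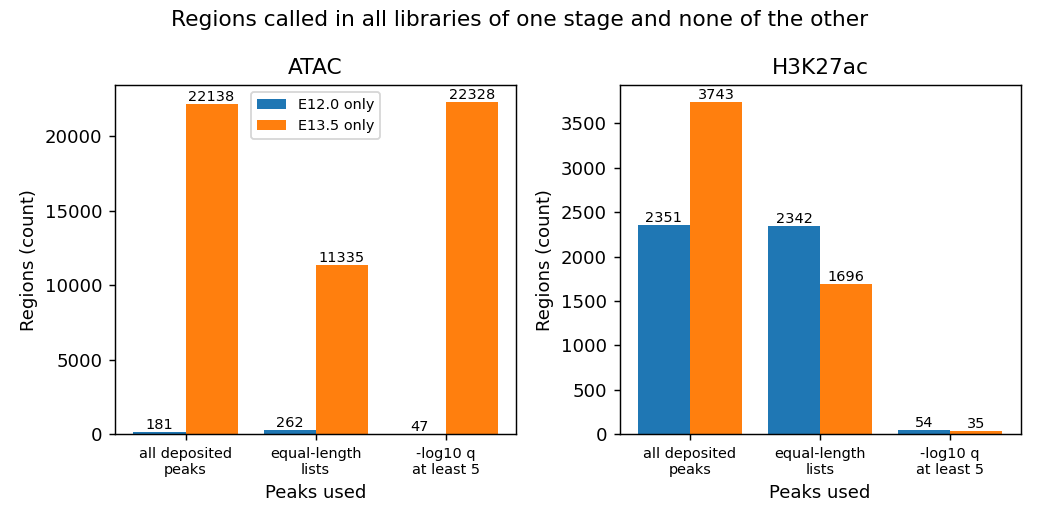
Number of merged regions called in all libraries of 1 stage and none of the other, for ATAC (3 libraries per stage) and H3K27ac (2 per stage), with all deposited peaks, equal-length lists and a stricter q. E13.5-only ATAC regions outnumber E12.0-only regions with all peaks (22138 against 181) and in equal-length lists (11335 against 262), while the larger side changes for H3K27ac.

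H3K27ac marks active enhancers and promoters. Regions with the mark at 1 stage only were found near Otx2, a homeobox gene, at E12.0 and in Nt5e, a Yap and Tead target, at E13.5. The Hippo kinase gene Stk3 had such regions at both stages. Of 267936 merged regions, 2351 were called in both E12.0 libraries only, 3743 in both E13.5 libraries only and 5266 in all 4. With equal-length lists the larger side changed, to 2342 at E12.0 and 1696 at E13.5, and at a −log10 q of at least 5 the counts were 54 and 35. Replicates shared little. The shared bases made up 0.107 of the bases in either list at E12.0 and 0.0512 at E13.5, against 0.254 between E12.0 replicate 1 and E13.5 replicate 1. E12.0 replicate 1 was made with another library kit than the other 3. Without it the counts were 68056 and 6562, and they were 30272 and 4607 without E12.0 replicate 2, 10411 and 60292 without E13.5 replicate 1, and 2752 and 77200 without E13.5 replicate 2. In each of these settings 1 stage had 1 library left, whose peaks counted without being seen in a replicate. The rise of the counts there does not judge the library left out. Near fixed-list genes, 31 E12.0-only and 35 E13.5-only regions were found in the main setting. The strongest at E12.0, by the smaller of the authors' fold values, lay 21322 bp from Otx2 (chromosome 14, 48634463 to 48635459, 3.71), 29955 bp from Frmd6 (chromosome 12, 70794871 to 70795501, 3.50), and inside Col3a1 (chromosome 1, 45315919 to 45316391, 3.36) and Wnt2b (chromosome 3, 104938165 to 104938705, 3.23). Among the strongest at E13.5, regions lay in Nt5e (chromosome 9, 88332058 to 88332700, 4.49), 7306 bp from Elavl4 (chromosome 4, 110359245 to 110359721, 3.89), and in Stk3 (chromosome 15, 34904326 to 34905221, 3.66), where it spans the E13.5-only ATAC region. An E12.0-only H3K27ac region lay 69 bp from an end of Stk3 (chromosome 15, 35155951 to 35156337, 2.47).

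Tead CUT&RUN regions, called at E12.0, lay in open chromatin more often than shifted positions did. The series holds no CUT&RUN library with a control antibody, and the Tead motif comparison was not run. Whether the overlap reflects Tead binding or cutting of open chromatin without it was therefore not tested. Regions held by both replicates were found near members of most of the fixed lists, while none was called near Ccn2 or Ccn1. The lists held 18250 and 58410 intervals, and 1590 merged regions were called in both. Of the intervals of replicate 1, 8.82% overlapped replicate 2, against 2.37% after a shift by 10 kb. Of the 1590 regions, 57.9% (95% Wilson interval 55.4 to 60.3) overlapped a region open in all E12.0 ATAC libraries, against 4.87% when shifted, and 53.1% (50.7 to 55.6) overlapped H3K27ac of both E12.0 libraries, against 3.24%. For the intervals of replicate 2 alone the shares were 29.5% and 25.7%, against 3.01% and 2.10% when shifted. For those of replicate 1 alone they were 6.69% and 5.42%, against 2.0% and 1.11% when shifted. The Wilson intervals do not cover this difference between the replicates. The 1590 regions overlapped regions open in all E13.5 ATAC libraries more often, at 69.9% against 8.52% when shifted. They overlapped H3K27ac of both E13.5 libraries less often, at 36.3% against 2.39%. Overlap with open chromatin was thus not particular to E12.0. Within 1 kb of an end of a protein-coding gene lay 32.6% of the 1590 regions, and 64.7% lay inside a gene span. Of the 33763 shared ATAC regions 948 held a Tead region, as did 68 of the 22138 E13.5-only regions and 0 of the 181 E12.0-only regions. These sets are not matched, with median widths of 895, 434 and 399 bp and 38.1%, 3.51% and 7.73% within 1 kb of a gene end. The replicates were made with different kits, and 428 of the regions were also in all 4 H3K27ac lists. Without those, 46.2% of the remaining 1162 overlapped E12.0 ATAC regions, and at a −log10 q of at least 5 there were 99 regions.

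**Figure D4:**
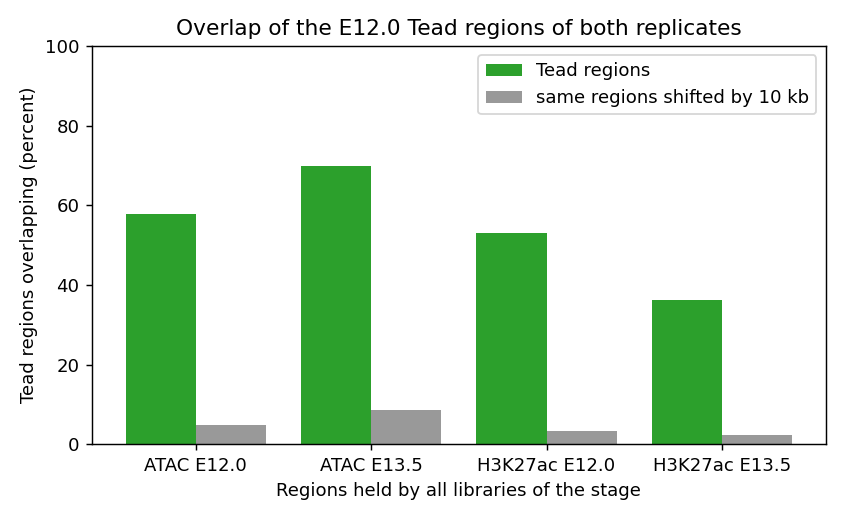
Percent of the 1590 Tead regions of both replicates that overlap regions held by all libraries of a stage (green), and percent after shifting them by 10 kb, as the mean of both directions (grey). Overlap with E12.0 ATAC regions is 57.9% against 4.87% when shifted.

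Tead regions within 50 kb of a gene span were found for 6 of 24 Yap and Tead targets (Arhgef17, Asap1, Axl, Dock5, Lats2 and Rbms3), 7 of 22 Hippo components, 3 of 13 G1 genes (Ccnd1, E2f2 and E2f3), 6 of 21 prosensory genes and 2 of 13 cell cycle inhibitors (Cdkn2c and Rb1). Several of these regions lay nearer an end of another gene. That gene was Id3 for E2f2, Xpo4 for Lats2, Cdca2 for Dock5 and Cyp2s1 for Axl. It was Nipsnap1 for Nf2 and Faf1 for Cdkn2c. The Id3 regions counted for both the G1 and prosensory lists, and the Xpo4 region for both the target and Hippo lists. Over all protein-coding genes the share was 13.3%. Of 10000 random lists matched on gene length, 13.6% had as many genes as the target list, 4.42% as many as the Hippo list, 5.05% as many as the prosensory list, 25.4% as many as the G1 list, 4.92% as many as the epithelial list (3 of 7 genes) and 5.21% as many as the list of Wnt targets (4 of 10), before any correction for the number of lists. No such region was called at Ccn2, Ccn1 or Myc, where replicate 1 had 0, 1 and 0 intervals within 50 kb and replicate 2 had 9, 7 and 0. The strongest list-gene region, by the smaller of the authors' fold values, lay across an end of Arhgef17 (chromosome 7, 100932147 to 100933204, 4.77). Those that followed lay in Vgll4 (chromosome 6, 114963777 to 114964525, 3.48), across an end of E2f3 (chromosome 13, 29985582 to 29986709, 3.18), in Wwc1 (chromosome 11, 35864401 to 35865618, 3.05) and in Lgr5 (chromosome 10, 115492851 to 115494368, 2.96). Further ones lay 9011 bp from Cdkn2c (chromosome 4, 109675767 to 109676256, 2.87), 24228 bp from Nf2 (chromosome 11, 4873772 to 4874453, 2.72), in Tead1 (chromosome 7, 112825745 to 112826900, 2.72), in Notch1 (chromosome 2, 26502533 to 26503198, 2.72) and 35815 bp from Dock5 (chromosome 14, 67714995 to 67716113, 2.602). The median fold over all intervals was 2.72 in replicate 1 and 2.19 in replicate 2. The regions near Nf2, in Tead1, in Notch1 and near Dock5 had folds of 2.72, 2.72, 2.72 and 2.602 in replicate 1. Their folds in replicate 2 were 3.58, 3.99, 2.83 and 2.99. Of the intervals, 40.3% in replicate 1 and 89.2% in replicate 2 passed a q of 5%. A place in this order therefore does not by itself mark strong binding in replicate 1. The 5 strongest Tead regions of all lay elsewhere. They were on chromosome X at 143482753 to 143483384, 34982 bp from Pak3 (28.1), on chromosome 4 at 64497696 to 64498234, 450681 bp from Tnc (19.8), on chromosome X in Cldn34d at 76598566 to 76599338 (15.5), on chromosome 12 at 74803876 to 74804611, 92606 bp from Kcnh5 (14.6), and in Dock2 at 34681546 to 34682559 on chromosome 11 (11.4). Of these 5, 4 were in all 4 H3K27ac lists and the other in 3, and the regions near Tnc and Kcnh5 and in Dock2 were in 0 of the 6 ATAC lists.

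The share of ATAC intervals that held a Tead region was 1.16 ± 0.126% at E12.0 and 0.889 ± 0.0205% at E13.5 (SD, n = 3 per stage, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). In equal-length lists the shares were 1.27 ± 0.0399% and 1.28 ± 0.0187% (exact permutation p = 0.9).

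Expression was then compared for the genes nearest these regions within 50 kb. Of 476 measured genes with a Tead region within 1 kb of an end, 107 rose and 120 fell, and of 449 with a more distant one, 89 rose and 113 fell. Their median log2 fold changes were 0.02, which was -0.03 with DESeq2 size factors, and -0.10, which was 0.74 on log2(TPM + 1), beside 0.05 over all genes with TMM scaling. Genes near E12.0-only ATAC regions numbered 67, of which 12 rose and 18 fell (median -0.26, and 0.65 on log2(TPM + 1)). Those near E13.5-only ATAC regions numbered 4336, with 948 up and 918 down (median 0.07). Near E12.0-only H3K27ac regions 217 of 966 rose and 241 fell (median -0.02, and 0.74 on log2(TPM + 1)), and near E13.5-only regions 224 of 1079 rose and 204 fell (median 0.08). None of the 6 gene sets was called by camera (smallest adjusted p = 0.887), 0 passed an unadjusted p of 0.05, 0 passed with an estimated correlation, and 0 passed with fry (smallest adjusted p = 0.173). Adjusted over the set alone, the counts higher and lower were 109 and 122 for Tead near gene ends, 87 and 111 for distant Tead, 12 and 19 for E12.0-only ATAC, 932 and 904 for E13.5-only ATAC, 219 and 242 for E12.0-only H3K27ac, and 211 and 193 for E13.5-only H3K27ac.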

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

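Removing mt-Rnr2, keeping protein-coding genes only, testing lists on log2(TPM + 1), using numbered chromosomes, X and Y only, combining equal lengths with 2 of 3 libraries and removing regions in all 4 H3K27ac lists were chosen after seeing the data. Where a cause is not given below, the cause was not tested. The RNA count of 7340 was 5251 to 6050 with a library left out (2341 to 2751 higher, 2910 to 3299 lower), where the lone library is assumed to vary like the other group and fewer samples enter. The higher count fell to 2341 without E12.0 replicate 1. With limma on log2(TPM + 1) 6806 were higher and 2309 lower, and 5374 of the 7340 calls were shared in direction. With DESeq2 6992 of the 7340 were shared. The replicate numbers share only a number: deviations of same-numbered libraries correlated across genes at 0.00816 (2 pairs), and with the replicate block 7138 genes were called, 6903 of them shared. Of 86 named genes called, 12 lost the call and 2 reversed on log2(TPM + 1) (Tead2 at 0.21, Cdkn1a at 0.47), and 3 to 10 lost it when 1 library was left out.

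Called lists were 4 in the main setting and with each library left out, 0 with an estimated correlation and 7 with fry, which asks another question. With the estimated correlation the medians were by construction those of the main setting (-1.94 for S phase, -3.24 for G2/M, -1.73 for G1), and the prosensory list was called by fry at 0.87. The estimated correlations were -0.0093 for S phase and -0.0758 for G1, below the preset 0.01, and 0.496 for G2/M. The S-phase and G1 calls were thus lost to the few degrees of freedom of that setting, not to correlation between genes. With a library left out medians ran from -2.06 to -1.63 for S phase, -3.46 to -3.09 for G2/M, -1.72 to -1.66 for G1, -0.62 to -0.43 for Yap and Tead targets and 0.59 to 0.91 for prosensory genes. On log2(TPM + 1) the G1 list lost its call (-0.71, adjusted p = 0.0652), and signs turned, with all genes at 0.75, for Yap and Tead targets (0.31), Hippo (0.38), Notch (0.39), nonsensory (0.74), medial (0.65), neurons (0.0165), mesenchyme (0.25), genes near E12.0-only ATAC (0.65) and H3K27ac (0.74), and genes with distant Tead regions (0.74).

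The other sign changes were in lists, sets or genes not called in the setting concerned. With DESeq2 size factors they were hair cell (-0.0161), supporting cell (-0.0203) and genes with Tead near an end (-0.0323). With no filter they were supporting cell (-0.0939), nonsensory (0.0702), medial (0.0630), genes near E12.0-only H3K27ac (0.0752) and distant Tead (0.0428). With the replicate block they were supporting cell (-0.0308), nonsensory (0.0715) and medial (0.0481). Without mt-Rnr2 they were Wnt targets (-0.13) and nonsensory (0.0018). With protein-coding genes only they were hair cell (-0.0209), supporting cell (-0.0244), Wnt targets (-0.19) and Tead near an end (-0.0375). Within 10 kb they were genes near H3K27ac at E12.0 only (0.12) and E13.5 only (-0.0304). With a library left out the ranges that crossed 0 were -0.27 to 0.43 for Ccn2, -0.36 to 1.55 for Tead3, -1.57 to 0.30 for Tead4, -0.0488 to 0.0701 for genes near E12.0-only H3K27ac, -0.12 to 0.0037 for distant Tead, -0.26 to 0.0419 for Wnt targets, -0.18 to 0.44 for cell cycle inhibitors, -0.92 to 0.11 for glia, -0.23 to 1.24 for hair cell, -0.43 to 0.0734 for medial, -1.38 to 1.78 for mesenchyme, -0.23 to 1.03 for nonsensory and -0.43 to 0.0636 for supporting cell. Genes with Tead near an end ran from 0.0277 to 0.0879.

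ATAC regions at 1 stage numbered 22319, and 11597 with equal-length lists (11335 at E13.5 only), 47627 with 2 of 3 libraries (44664 and 2963), 47 at E12.0 only at the stricter q and 3382 at E12.0 only with equal lengths and 2 of 3. With a library left out they were 26220 to 37395, with 230 to 1294 at E12.0 only and 24926 to 36378 at E13.5 only. E13.5-only regions outnumbered E12.0-only ones in each of these. For H3K27ac, leaving out a library leaves 1 library in its stage, whose peaks then count without a replicate. H3K27ac regions at 1 stage numbered 4038 with equal-length lists (1696 at E13.5 only), 89 at the stricter q (54 and 35) and 34879 to 79952 with a library left out (2752 to 68056 at E12.0 only, 4607 to 77200 at E13.5 only). Tead regions in both replicates were 99 at the stricter q, 767 with 50% overlap and 1036 with equal-length lists, and single lists held 18250 to 58410. Their share in E12.0 ATAC regions was 47.5% with 50% overlap, 75.4% with equal lengths, 46.2% without regions in all 4 H3K27ac lists and 6.69 to 29.5% in single lists. Their share in E12.0 H3K27ac was 67.7% at the stricter q, 42.5%, 70.8% and 35.9% in those same settings, and 5.42 to 25.7% in single lists. The 5 alternatives for the Tead motif were not run. Depth limits low genes: 10 reads were 0.424 to 1.38 CPM.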

Other observations

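The tests on gene length, on the most abundant genes and on mt-Rnr1 were set before their values were seen, and the tests on random lists, mitochondrial mRNAs and the strongest ATAC intervals were chosen after, as were the genes and shares in the next paragraph, while equal-length lists and library splits were set beforehand and only the limits for reading them were written after.

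Some shares of the counts are given as values, without a test. Pseudogenes of ribosomal proteins took 0.394% and 0.289% of the counts in the E12.0 libraries and 0.136% and 0.169% at E13.5, and all pseudogenes 2.02% and 1.76% against 1.52% and 1.64%. The nuclear RNA Malat1 took 0.0199% and 0.0207% at E12.0 against 1.22% and 0.55% at E13.5. The 10 most abundant genes took 20.4% and 16.3% of the counts at E12.0 and 4.41% and 4.01% at E13.5, a difference that lies in mt-Rnr2 with 17.0% and 13.2% at E12.0.

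At the Hippo kinase gene Stk3 the RNA rose at E13.5, by 0.91 ± 0.28 on the log2 scale (SE, edgeR adjusted p = 0.0228, n = 2 per stage), and a region in its span was called at E13.5 only in both ATAC and H3K27ac. An H3K27ac region 69 bp from its end went the other way, called at E12.0 only. Stk3 was singled out after its values were seen. Yap1, Amotl1 and Kif20b were also nearest to 1 of the 5 strongest E13.5-only ATAC regions near list genes. With TMM scaling their RNA was lower at E13.5, with log2 fold changes of -1.37, -1.53 and -1.31. Of all 4336 measured genes near E13.5-only ATAC regions, 948 rose and 918 fell.

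For the fall of the G2/M genes, the list median after removing the trend of fold change on effective length was -3.43 (members -5.13 to -1.28), against -3.24 (members -5.20 to -1.30) before. With 22 genes left out, the 10 most abundant of each library, it was -3.23, but each member moved by 0.0127 to 0.0130, so this decides nothing about a few genes taking most of the counts. Of 10000 random lists matched on mean expression, 0% had a median as low. These lists were drawn after TMM scaling, with the median of all genes at 0.05, so they cannot show a shift that scaling removed. They show that the list fell relative to genes of like expression, which a shift common to all genes would not give. The trend with length is thus excluded as the whole source. A shift common to all genes is excluded only for the fall relative to other genes. Age, the choice of p27-GFP cells and RNA or library quality stay open, as untested, and cannot be separated in this design, since the shares of mt-Rnr2 (17.0% and 13.2% against 0.295% and 0.18%) and Malat1 (0.0199% and 0.0207% against 1.22% and 0.55%) and the length minus effective length (146 and 141 against 189 and 188 bases) differ between the same stages.

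The lower level of mt-Rnr2 at E13.5, a log2 fold change of -6.58 ± 0.50 (SE, edgeR adjusted p = 1.25e-05), was another pattern. The 13 mitochondrial mRNAs had a median of 2.14, which argues against a like fall of all mitochondrial RNAs. These mRNAs took 0.458% and 0.495% of the counts at E12.0 and 1.90% and 1.30% at E13.5. Against 17.0% and 13.2% for mt-Rnr2 at E12.0 this rise is small. The share of mitochondrial RNA in sum was thus lower at E13.5, among counts after poly(A) selection. That share does not give the RNA content of the cells. If less ribosomal RNA were carried through poly(A) selection, mt-Rnr1 could fall too. It had a log2 fold change of -1.19 ± 0.34, close to the limit of -1 set for the test, so this source cannot be told apart from others. A difference in RNA processing with age was not tested.

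For the excess of ATAC regions at E13.5 only, in equal-length lists the ratio of E13.5-only to E12.0-only regions was 43.3, and 6.47 (21867 against 3382) when 2 of 3 libraries sufficed, which argues against list length as the whole source. Of the strongest 1000 intervals of each E13.5 library, a mean of 0.0333% were in none of the E12.0 lists, against 2.1% for the reverse. Of the strongest 20000 the mean was 1.26% against 0.415%, and 83.3 to 88.9% of them were in all 3 E12.0 lists against 98.7 to 99.6% for the reverse, so the answer turns on the number of intervals chosen. Lower sensitivity of the E12.0 libraries cannot be told apart from a change with age, which stays open as untested, and the authors' filters also differed between the stages. Of the 10 splits of the 6 libraries, 1 gave as many regions (the real one, 22319, with 2176 as the highest of the others), and 10 splits are too few for a share under 0.05.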
